A study of Caenorhabditis elegans with 60 samples.

How the data were processed

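The series holds 60 samples in 8 sets, all from Caenorhabditis elegans. Small RNA libraries came from dissected gonads, whole animals of several stages, embryos, RNAi-treated animals and immunoprecipitates of the Argonautes HRDE-1, WAGO-1 and RDE-1, and mRNA libraries came from dissected gonads. Each sample was placed in its group by its title, and replicate numbers were taken from the titles. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, small RNAs were size-selected on gels, treated with RNA polyphosphatase so that triphosphorylated 22G-RNAs could be captured, and in some samples oxidized with sodium periodate, which spares RNAs methylated at their last nucleotide. The mRNA libraries were depleted of ribosomal RNA and made with a directional kit.

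Per the submitters' processing notes, the tools named for the gonad mRNA libraries were Trimmomatic 0.35, STAR 2.5.0a, RSEM 1.3.0 and DESeq2 1.18.1. DESeq2 1.18.1 alone was named for the gonad small RNA and oxidation libraries, and no tool for the others. The aligner of the small RNA tables and the genome build are not given in the sources used here. The deposited tables of gonad small RNAs, gonad mRNAs and oxidation carry DESeq2 counts in their names and hold a normalized signal per feature. Those of stages, immunoprecipitates and pos-1 RNAi also hold a normalized signal, whose scaling is not given in the sources used here. The deposited embryo tables hold an expected count per feature and read length, not all whole numbers. Features carry the authors' class: WAGO loci (22G-RNA loci dependent on mutator genes), CSR-1 loci, ALG-3/4 loci, ERGO-1 loci, piRNAs and microRNA arms. The gonad small RNA table lists 21815 features, among them 2434 WAGO loci, 3640 CSR-1 loci, 15366 piRNAs and 375 microRNAs. The mRNA table lists 22844 features, of which 21431 matched a gene of the reference name table and 587 are transposons. That table served for names only, and no coordinates are given. Reads of near-identical copies, such as histone genes, transposons and clustered piRNAs, may have been split between them by the authors' counting.

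For the normalized tables, log2 of the value plus a pseudocount of 1 was fitted per feature with limma 3.58.1 (trend on the mean) in R 4.3.3, over features with a mean of at least 10. Fold changes are on that log2 scale, which understates the change of low features. P-values were adjusted by the Benjamini-Hochberg method, and features under 0.05 were called. Expected counts of embryos were summed over lengths, rounded and fitted with the quasi-likelihood test of edgeR 4.0.16, with piRNAs and WAGO loci in 1 fit under TMM scaling. DESeq2 1.42.0 served as an alternative. The values of the gonad small RNA and oxidation tables were whole multiples of a step per library for 100% of values (tolerance 0.1). The edgeR test on these recovered reads, added after seeing the data, called 7756 features in gonads, 9097 in oxidized wild type and 6177 in oxidized rde-1.

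The stage series had 1 library per genotype and stage, so henn-1 was tested across 3 stages with stage as a covariate. The HRDE-1, WAGO-1 and pos-1 RNAi sets had 1 library per group and were described as ratios without a test. Their values turned out to be normalized and not counts, so the Poisson intervals planned for them were left out. The wild type and rde-1 oxidation tables were each normalized by themselves, per the deposited values. The difference between genotypes was therefore taken between effects within each table. Two-sided exact permutation tests were used for class shares, where 3 libraries against 3 give no p below 0.1. Of the set tests, camera used a preset correlation of 0.01 and, as an alternative, an estimated correlation, and fry served as another alternative. Gene lists, comparisons, tests and most alternatives were fixed before the data were examined. The 28 lists cover Argonautes, piRNA biogenesis, the mutator and 22G-RNA machinery, nuclear RNAi and chromatin, P granules, oogenesis, spermatogenesis, meiosis and germline, histones, cell death, heat shock, immunity, ERGO-1 targets, transposons, RDE-1 targets, somatic tissues and microRNA families. The transposon list matched no tested feature by name, so transposons are given as the tables class them, and the RDE-1 target list has a single member, Y47H10A.5.

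Named features followed a fixed rule. The targeted gene came first, then up to 6 largest increases and 6 largest decreases among called features whose groups did not overlap and whose higher mean passed the table median (10 CPM in embryos). Then came up to 3 members of lowest adjusted p per list, in order of the camera p, until about 25 were named. In unreplicated sets, the 3 largest ratios each way were named, with mir-243 and Y47H10A.5 in addition. Near-identical copies were treated as a family. Names outside the rule were chosen after their values were seen, and each such place says so.

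Totals of the normalized values ran from 4671868 to 5094090 in gonad small RNA libraries (4215264 to 8745475 recovered reads) and from 15318171 to 16159369 in gonad mRNA libraries. They ran from 8837926 to 11853570 in the oxidation set (6311071 to 13613629 recovered reads), 66278 to 654643 in the RDE-1 set, 149059 to 323500 in the stage set and 511291 to 678659 in the HRDE-1 and WAGO-1 set. Embryo libraries held 967644 to 3829632 reads of piRNAs and WAGO loci. Replicates differed by more than counting noise in each pair checked (chi-square per degree of freedom of at least 3.41), so no library was treated as a duplicate. Floors from counts of 0 (3 counts over the group) cover counting error only.

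The tests were tried on simulated data with 200 changed features (seed 1), fewer in the RDE-1 set. Changes went up or down at random, so scaling was not tried where most features move in the same direction. For gonad small RNAs, 80.6% of 2-fold and 92.5% of 4-fold changes were recovered over 9410 features, and for gonad mRNAs 73.1% and 92.5% over 8697. In the oxidation set, recovery of 4-fold changes was 41.8% in wild type (12152 features), 50.7% in rde-1 (11758) and 29.9% for their difference (12086). In the RDE-1 set, 12 features per comparison had 16-fold changes. Of these, 66.7% were recovered in otherwise wild type animals (163 features tested), 83.3% in henn-1 (158) and 33.3% for the difference (155). The stage series recovered 74.6% of 2-fold changes (2079 features). The embryo fit recovered 5.97% of 2-fold and 83.6% of 4-fold changes (7506 features), with 10.2% false calls. Alternatives covered scaling (TMM, library totals, RLE), filters, pseudocounts of 0.5 and 10, a count test, leaving out each library, the replicate number as a block and, for embryos, the library protocol. A pair of numeric columns was not used (2 in all), which hold the authors' own ratios of immunoprecipitate to input.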

Results

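The study concerns HENN-1, the C. elegans member of the HEN1 family, which methylates the last nucleotide of some small RNAs. Its substrates include piRNAs (bound by the germline Argonaute PRG-1) and primary small RNAs bound by ERGO-1. The 60 samples form 8 sets. Small RNAs and mRNAs were sequenced from gonads dissected from gravid adults grown 68 to 70 h at 20 C, with 3 wild type and 3 henn-1 mutant libraries of each kind. WAGO loci, which template the secondary 22G-RNAs bound by worm-specific Argonautes, were measured in embryos, at 52 h (L4 larvae) and at 68 h (gravid adults), with 1 library per genotype and stage. Embryo piRNAs and WAGO loci were also counted by read length in 3 wild type and 3 henn-1 libraries. Wild type and rde-1 animals gave 3 libraries each with and without periodate. Immunoprecipitates (IP) of RDE-1 with matched inputs came in duplicate from animals with and without henn-1. IPs of HRDE-1 and WAGO-1 and the libraries of animals fed double-stranded RNA against pos-1 had 1 library per group. Gonad small RNA libraries held 4215264 to 8745475 recovered reads, the oxidation libraries 6311071 to 13613629 and the embryo libraries 967644 to 3829632 counted reads. The depth of the RDE-1, stage, HRDE-1, WAGO-1 and pos-1 libraries is unknown.

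The first comparison asked which small RNAs depend on henn-1 in the gonad. The henn-1 gene (C02F5.6) was checked first: its mRNA was 2192, 2240 and 2298 in the wild type gonad libraries and 234, 249 and 229 in the henn-1 libraries (log2 change -3.24, SE 0.05, adjusted p = 2.4e-10, n = 3 per group). 22G-RNAs antisense to henn-1 fell as well, from 194 ± 35.5 to 109 ± 8.12 (log2 -0.82, SE 0.14, adjusted p = 0.000506). Those of rde-1 (K08H10.7), which encodes the Argonaute that starts RNAi from foreign double-stranded RNA, were 590.0 ± 45.4 and 587 ± 32.8 (log2 -0.01, SE 0.08, adjusted p = 0.951). piRNAs took 3.30% ± 0.16 of listed reads in wild type gonads and 16.0% ± 0.72 in henn-1 gonads (4.83-fold), and WAGO loci took 50.6% ± 1.34 and 39.9% ± 1.38 (SD, n = 3). CSR-1 loci, whose 22G-RNAs match expressed germline genes, went from 44.5% ± 1.2 to 42.3% ± 0.53. The groups did not overlap in these 3 classes (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). microRNAs took 1.65% and 1.82% (exact p = 0.4).

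Single piRNAs showed the same direction. Of 3448 tested piRNAs, 3354 rose and 3 fell, with a median log2 change of 2.90. The largest increase was in 21ur-1424, from 2.48 ± 0.78 to 445 ± 108 (log2 7.0, SE 0.25, adjusted p = 1.4e-08). The next were 21ur-2266 (log2 6.22), 21ur-4437 (6.07), 21ur-10966 (6.04), 21ur-3225 (5.99) and 21ur-3481 (5.90). The increase of piRNAs and the decrease of WAGO loci held under each scaling tried. TMM factors gave 3164 piRNAs higher and 6 lower, with a median of 2.65.

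WAGO loci lost 22G-RNAs at 1319 of 2387 tested loci and gained them at 282 (median log2 -0.36). Y34D9A.8 fell from 1029 ± 65.5 to 10.3 ± 0.59 (log2 -6.51, SE 0.12, adjusted p = 5.8e-10). R04A9.7 (-5.39), exc-9 (-5.39), F10E9.2 (-5.38), gtf-2A2 (-5.11) and C09G5.7 (-4.68) followed. gtf-2A2 encodes a subunit of the general transcription factor TFIIA, and it went from 901 ± 25.2 to 25.1 ± 2.29. Among WAGO loci, 103 of 191 transposons fell and 4 rose, and 103 of 171 pseudogenes fell and 13 rose. CSR-1 loci had 317 higher and 179 lower of 3542 as deposited (median 0.04), but the direction of this class flipped with TMM factors (21 higher, 1643 lower, median -0.21), with library totals (117 and 420, median -0.04) and with recovered reads (23 and 1507, median -0.20). The microRNA class (23 of 79 higher, none lower, median 0.24) went to a median of -0.01 under TMM.

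Some members of several fixed lists of germline genes fell in their 22G-RNAs. The camera test called 5 lists, and none of these calls held with an estimated correlation (adjusted p = 0.761 for each). It compares a list with all tested features, of which 3448 were piRNAs with a median log2 change of 2.90. No list was tested against its own class, so these calls do not set any list apart from CSR-1 or WAGO loci. Oogenesis genes fell at 10 of 30 members and rose at none (7 adjusted over the list alone), led by the RNA-binding protein gene puf-5 (log2 -0.49), the chondroitin proteoglycan gene cpg-3 (-0.73) and the fertilization gene egg-2 (-0.33). The camera test called this list with adjusted p = 0.00262. Replicative histone genes fell at 7 of 10 members (7 over the list alone), with his-37 going from 211 ± 18.4 to 67.4 ± 7.82 (log2 -1.64, SE 0.13). The copies his-50 and his-28, which share their values, fell by 0.78 on the log2 scale (camera adjusted p = 0.00276 for the list). ERGO-1 target genes fell at 8 of 17 members and rose at 1, both counts the same adjusted over the list alone (median -0.32). H16D19.4 (-0.86), E01G4.5 (-0.93) and W05H12.2 (-0.62) were named, and the camera adjusted p was 0.00413. All tested members of the histone list (median -0.72) and the ERGO-1 target list are WAGO loci, of which 55.3% fell (median -0.36, quartiles -0.91 and -0.07). Both medians lay within these quartiles, so these calls do not set either list apart from the class. Argonaute genes fell at 3 of 15 (3 over the list alone), namely wago-2 (-0.47), ppw-1 (-0.24) and prg-2 (-0.21), with camera adjusted p = 0.0256. Genes of piRNA biogenesis fell at 3 of 11 and rose at 1 (3 and 0 over the list alone), with camera adjusted p = 0.0323. Among lists that were not called, P granule genes fell at 1 of 15, meiotic and germline genes rose at 2 of 28, and the mir-51 family rose at 4 of 7 arms (4 over the list alone, median log2 0.47).

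In all, limma called 5477 of 9456 small RNA features, 3976 higher and 1501 lower. Higher features made up 72.6% of calls as deposited, 64.5% with library totals, 56.6% with recovered reads and 49.1% with TMM factors. The median of all features was 0.14, 0.05, -0.04 and -0.12 in the same order. Changes smaller than the gap between 0.14 and -0.12 can reverse between scalings, so they have no settled direction.

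**Figure D1:**
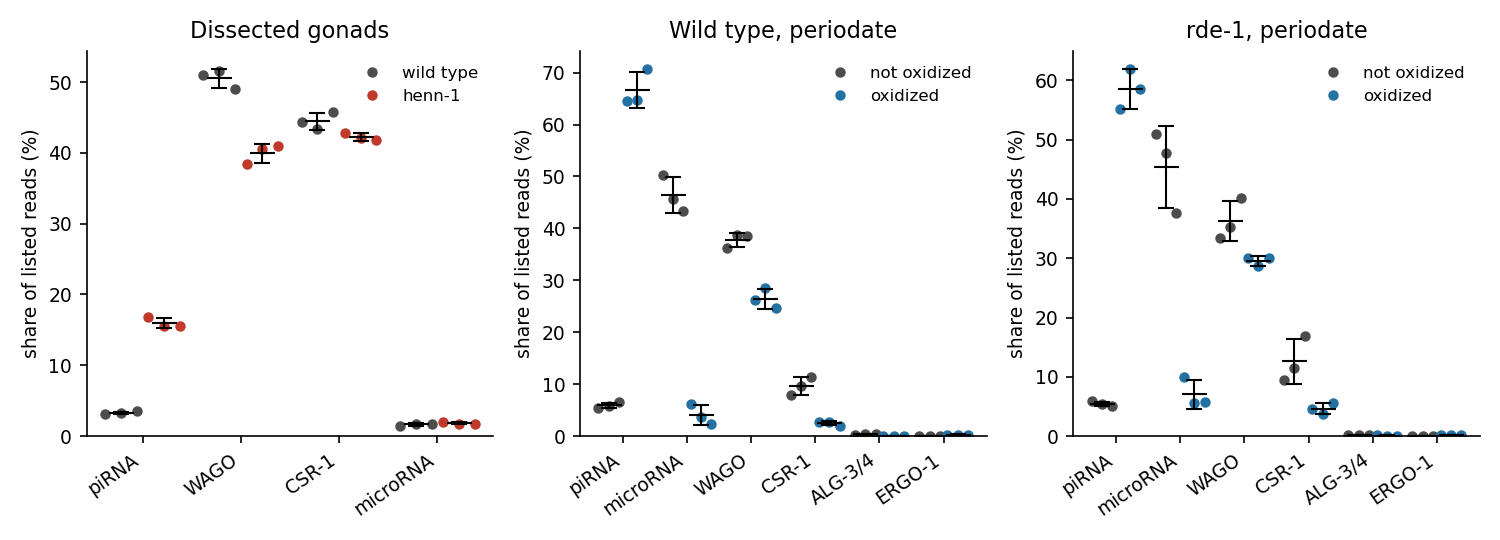
Share of listed reads per library (percent, vertical axis) for each small RNA class; dots are libraries, and the bar and whiskers are the mean and SD of 3 libraries. piRNAs took 3.30% of reads in wild type gonads and 16.0% in henn-1 gonads, and 66.7% of reads after periodate in wild type and 58.5% in rde-1.

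The mRNAs of the same kind of gonads were compared next, to see which transcripts change without henn-1. Part of the histone and muscle transcripts were higher, as were 6 of 46 tested transposons. Part of the transcripts of oocyte (16 of 34), P granule (9 of 18), Argonaute (9 of 21) and chromatin genes (8 of 22) were lower by small amounts. None of these gene list calls held with an estimated correlation (adjusted p = 0.270 to 0.294). The copies his-44, his-11 and his-15, which share their values, went from 3256 ± 265 to 5905 ± 401 (log2 0.86, SE 0.07, adjusted p = 0.000104, n = 3 per group). dhs-21, which encodes a short-chain dehydrogenase, went from 7.95 ± 2.48 to 78.3 ± 7.07 (log2 3.18, SE 0.28, adjusted p = 0.000167). The mRNA of pole-3, a predicted subunit of DNA polymerase epsilon, fell from 512 ± 59.2 to 155 ± 13.9 (log2 -1.71, SE 0.10, adjusted p = 3.4e-05). The mRNA of rde-1 was 3968 ± 98.3 and 3657 ± 143 (log2 -0.12, adjusted p = 0.0668). That of rde-1 passed the test with TMM factors (-0.13) and without henn-1 library 3 (-0.15).

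Replicative histone mRNAs rose at 34 of 63 members and fell at none (46 higher adjusted over the list alone, median log2 0.41). The camera test called the list with adjusted p = 1.6e-21 (adjusted p = 0.286 with an estimated correlation). Copies that share their values, such as his-44, his-11 and his-15, each count as a member. These counts and the camera p therefore overstate the evidence. Muscle genes, markers of tissue outside the germline, rose at 11 of 16 members (14 over the list alone, median 0.80). myo-3, a muscle myosin heavy chain, went from 58.1 ± 9.64 to 155 ± 29.5 (log2 1.39, SE 0.17), and the troponin genes unc-27 and mup-2 rose by log2 1.11 and 0.88. Its camera adjusted p was 6.0e-08 (adjusted p = 0.286 with an estimated correlation). Summed muscle transcripts were 1699, 1436 and 1510 in wild type libraries 1 to 3 and 2490, 2317 and 3244 in henn-1 libraries 1 to 3. Other markers of body tissue did not pass: limma called 0 of 6 intestine genes (median -0.58, camera adjusted p = 0.531), 0 of 8 epidermis genes (0.41, adjusted p = 0.767) and 0 of 7 neuron genes (0.18, adjusted p = 0.573). At an unadjusted p below 0.05 these counts were 0, 2 and 1. Somatic gonad genes rose at 5 of 12 and fell at 2 (6 and 2 over the list alone), with camera adjusted p = 0.0716.

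Oogenesis mRNAs fell at 16 of 34 members and rose at 1 (22 and 1 adjusted over the list alone, median -0.15). Among them were the polarity gene mex-6 (-0.35, SE 0.06), the yolk receptor gene rme-2 (-0.25, SE 0.04) and the egg activation gene egg-4 (-0.17, SE 0.03). camera gave adjusted p = 3.3e-07 for the list (adjusted p = 0.294 with an estimated correlation). Genes of nuclear RNAi and chromatin fell at 8 of 22 (11 over the list alone), among them the histone methyltransferase genes set-25 (-0.22) and mes-4 (-0.20) and the demethylase gene spr-5 (-0.28). Their camera adjusted p was 0.000179 (adjusted p = 0.294 with an estimated correlation). P granule genes fell at 9 of 18 (10 over the list alone, camera adjusted p = 0.000564, and adjusted p = 0.270 with an estimated correlation). Genes of the mutator and 22G-RNA machinery fell at 8 of 30 and rose at 1 (12 and 2 over the list alone, camera adjusted p = 0.000564, and adjusted p = 0.449 with an estimated correlation). Argonaute genes fell at 9 of 21 (11 over the list alone), with wago-2 (-0.22), prg-2 (-0.33) and ppw-1 (-0.20) among them (camera adjusted p = 0.00598, and adjusted p = 0.286 with an estimated correlation). Meiotic and germline genes fell at 10 of 30 (11 over the list alone, camera adjusted p = 0.00149, and adjusted p = 0.286 with an estimated correlation). Cell death and DNA damage genes fell at 5 of 16 and rose at 1 (6 and 1 over the list alone, camera adjusted p = 0.0491, and adjusted p = 0.294 with an estimated correlation). Called lists kept their direction under each scaling tried.

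Spermatogenesis genes had a median log2 difference of 0.92, with 1 of 49 higher and none lower (0 and 0 over the list alone). The camera adjusted p was 0.00131, with adjusted p = 0.742 with an estimated correlation and 0.460 by fry. Their summed transcripts differed within groups: 4282, 5805 and 4062 in wild type libraries 1 to 3 and 5344, 4537 and 7608 in henn-1 libraries 1 to 3. Wild type library 2 and henn-1 library 3 were the richest in sperm transcripts of their groups. Without both, 6 of 37 sperm genes, 7 of 16 muscle genes and 29 of 63 histone genes were higher, and 6 of 34 oogenesis genes were lower. egg-4 no longer passed without them (-0.17). No call was made by camera for piRNA biogenesis genes (1 higher, 2 lower of 15, adjusted p = 0.799), heat shock genes (3 lower of 14, with 2 higher and 4 lower over the list alone, adjusted p = 0.746), immune genes (0 of 4 by limma and 1 at an unadjusted p below 0.05, adjusted p = 0.990) or ERGO-1 targets (1 higher of 7, adjusted p = 0.746).

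Transposon transcripts passed the test at 7 of 46 measured elements, 6 higher and 1 lower. WBTransposon00000001 was listed at 0 in each wild type library and at 7.35 to 181 in the henn-1 libraries (adjusted p = 0.00691). Its call ended without henn-1 library 2. WBTransposon00000003 went from 7.20 ± 12.5 to 122 ± 87.2 (log2 5.22, SE 1.06, adjusted p = 0.0110), and WBTransposon00000005 from 19.2 ± 27.6 to 117 ± 60 (log2 3.87, SE 1.1, adjusted p = 0.0352). The last call ended without wild type library 1 (3.91) or 3 (2.4) or henn-1 library 1 (4.21) or 2 (3.49), and in the count test (2.59). The features named trY6B3B.8 and trK09F6.2, whose kind is not given in the sources used here, rose, the first from 0 in each wild type library to 16.8, 50.8 and 37.5 and the second from 0.360 to 23.4. trC04F12.11 fell from 34.4 to 1.40. fbxa-192, an F-box gene, fell from 421 ± 28.3 to 141 ± 33.1 (log2 -1.60, SE 0.15, adjusted p = 0.000231). ugt-48 (-1.33) and Y53C10A.2 (-1.27) passed narrowly. The ugt-48 call ended without any of wild type libraries 1 (-1.28), 2 (-1.37) and 3 (-1.33) or henn-1 libraries 2 (-1.26) and 3 (-1.09), and the Y53C10A.2 call ended without any single library (-1.13 to -1.41).

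In all, 1733 of 8750 mRNAs passed, 651 higher and 1082 lower. Of these, 64 rose and 12 fell at least 2-fold. Higher mRNAs made up 37.6% of calls as deposited, 30.7% with TMM factors and 58.4% with library totals (946 higher, 675 lower). The number called was 826 without wild type library 2, 697 without wild type library 3 and 676 without henn-1 library 2, and 971 without both sperm-rich libraries.

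**Figure D2:**
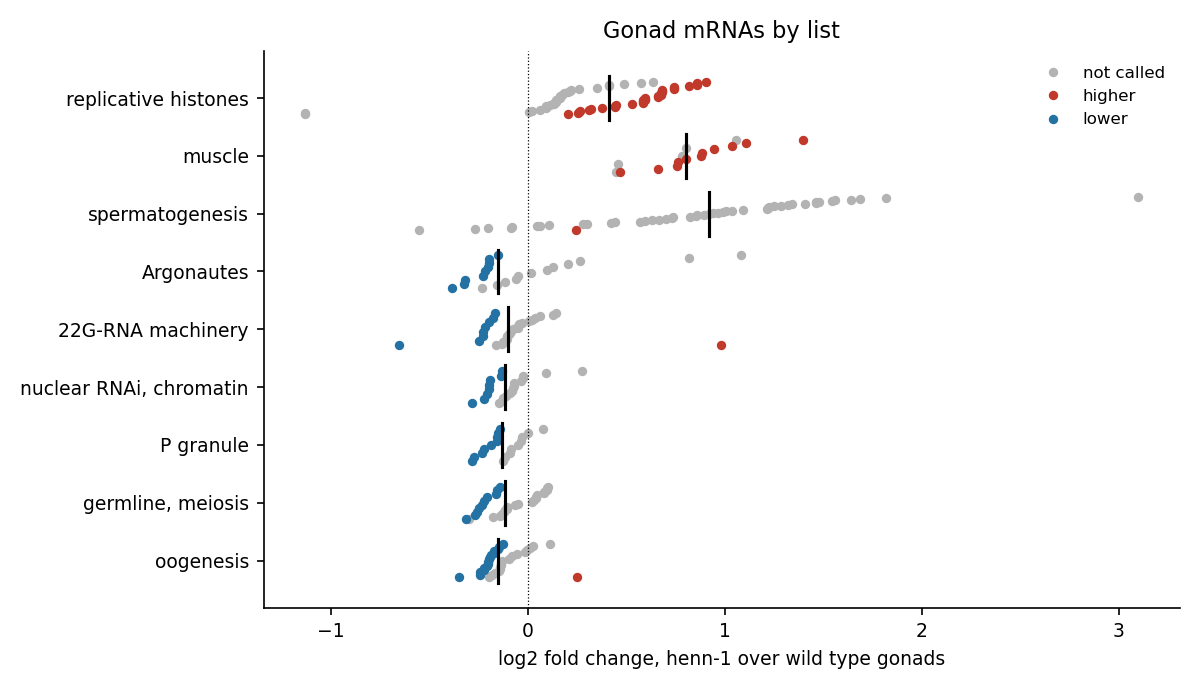
Log2 fold change of henn-1 over wild type gonad mRNAs (horizontal axis) for the members of 9 fixed lists; each dot is a gene, coloured by whether it was called higher, lower or not at all, and black lines are list medians. Of 63 histone genes, with copies of shared values counted separately, 34 were higher, and of 34 oogenesis genes 16 were lower. The spermatogenesis median of 0.92 is over all tested members, of which 1 was called.

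Setting both gonad data sets side by side, loci with the largest loss of 22G-RNAs had no called mRNA change where the mRNA was measured. The mRNA of gtf-2A2 differed by log2 0.38 (adjusted p = 0.118), that of C09G5.7 by 0.55 (adjusted p = 0.201), that of F10E9.2 by -0.53 (adjusted p = 0.0936) and that of R04A9.7 by 0.36 (adjusted p = 0.390). Some genes, chosen after their values were seen, changed in both. 22G-RNAs of rde-11, which encodes a factor of the RNAi machinery, rose from 1732 to 3676 (log2 1.09, SE 0.07) while its mRNA fell from 644 to 408 (log2 -0.66, SE 0.05, adjusted p = 0.000104). tpk-1, a thiamine pyrophosphokinase gene, gained 22G-RNAs (log2 1.5) and lost mRNA (-0.51, adjusted p = 0.00590). atgp-1 gained both (log2 1.98 and 0.66). his-37 lost 22G-RNAs (-1.64) and gained mRNA (0.53, adjusted p = 0.00291), and pole-3 lost both (22G-RNAs -0.69, adjusted p = 0.00241).

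The stage series asked whether WAGO loci lose 22G-RNAs outside the dissected gonad. Summed over WAGO loci, henn-1 had 72.6% of the wild type signal in embryos, 62.4% at 52 h and 71.3% at 68 h. With stage as a covariate, 916 of 2090 loci fell and 77 rose (median -0.58). gtf-2A2 fell most (log2 -4.65, SE 0.39, adjusted p = 0.00256), then Y32G9A.2 (-4.57), the insulin-like peptide gene ins-17 (-4.1), Y34D9A.8 (-3.84), F36A2.3 (-3.62) and ZK909.3 (-3.42). atgp-1 rose most (log2 2.69, SE 0.42, adjusted p = 0.00622), then dyf-3 (2.47), B0261.8 (2.35), C39F7.5 (2.24), tpk-1 (2.17) and W05F2.4 (2.16). rde-11 rose from 217 to 1475 in embryos and from 150 to 254 at 52 h (log2 1.47 over the stages, adjusted p = 0.0311). The ERGO-1 targets ZK402.5 (-1.62), ZK402.3 (-1.54) and ZK402.2 (-1.47) were among 7 of 20 members that fell (6 over the list alone). his-37 (-1.93) and his-31 (-0.90) fell among 4 tested histone genes (2 over the list alone), and the sperm gene spe-41 fell (-1.81).

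No list passed camera in the stages (adjusted p of 0.933 to 0.999). Genes of the mutator machinery had smut-1 at -0.86 (adjusted p = 0.0806) and rrf-2 at -0.66, neither called over all loci. The pals genes, of a family linked to the response to intracellular pathogens, had pals-25 at -1.33 (adjusted p = 0.0585), pals-22 at -0.67 and pals-14 at -0.51. pals-25 passed with any single stage left out (-0.63, -1.83 and -1.54), and his-31 no longer passed without 52 h (-1.0) or 68 h (-1.03). Lower loci dominated as deposited, with 7.8% of 993 calls higher. The shares were less unequal with TMM factors (42.3%, 192 higher and 262 lower) and library totals (37.1%, 171 and 290). The median of all loci was 0.03 and -0.04 there. This follows from the construction, since the table holds WAGO loci alone and both scalings centre them near 0, so it does not bear on the direction of the class. Without the 68 h pair 561 loci were called, without 52 h 705 and without embryos 1301.

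Many loci changed in both gonads and stages. Of 1972 WAGO loci tested in both and in embryos, 1056 fell in gonads, 863 across stages and 733 in both, where independent lists would share 462. Increases were shared at 65 loci (10.2 by independence), and 6 loci moved in opposite directions. Of the loci named as largest changes across stages, B0261.8 rose there but fell in gonads (log2 -0.77, adjusted p = 0.0259). F36A2.3 fell across stages and was not called in gonads (-0.15, adjusted p = 0.251). The others were called in the same direction in gonads. Across loci, which are not independent replicates, Spearman's correlation of the log2 changes was 0.774 between gonads and stages. Of 112 loci that fell at least 4-fold in gonads, 50 did so across stages. They include a pair chosen after their values were seen: cdh-12, a cadherin gene (log2 -3.51 in gonads and -3.25 across stages), and daf-7, which encodes a ligand of the TGF-beta family (-2.93 and -2.76).

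**Figure D3:**
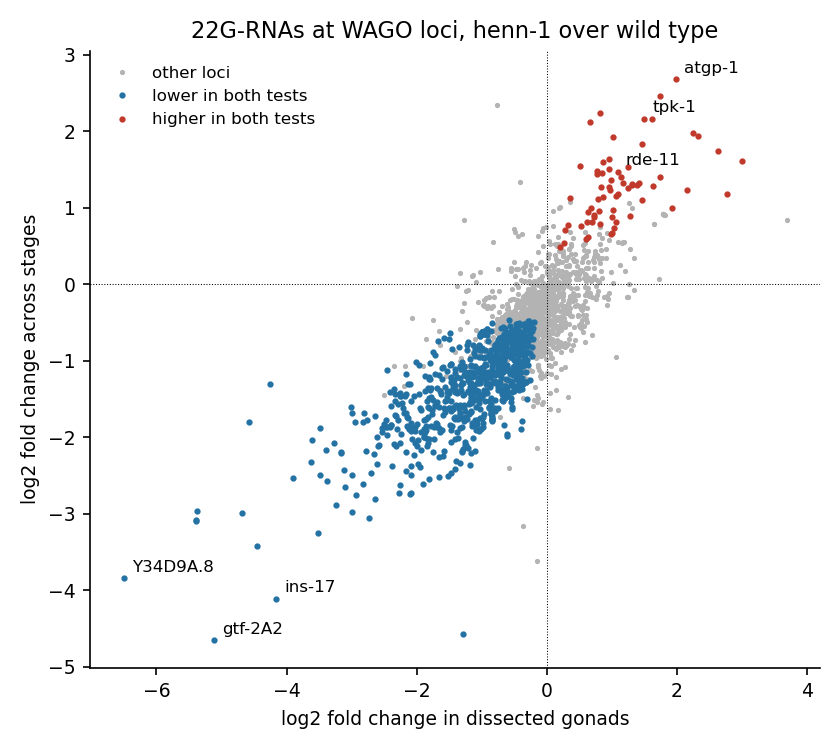
Log2 fold change of henn-1 over wild type at each WAGO locus in dissected gonads (horizontal axis) against the change across 3 stages (vertical axis), with loci lower in both tests in blue and higher in both in red. The change was shared downward at 733 loci and upward at 65; under TMM factors the median of all loci across stages moved from -0.58 to 0.03.

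Embryos were used to compare read lengths and the balance of piRNAs and WAGO loci. piRNA reads averaged 394574 ± 39825 in wild type and 1624680 ± 161130 in henn-1 embryos, and WAGO locus reads 2413200 ± 1570370 and 249653 ± 72401 (n = 3 per group). There were 1.68, 7.26 and 8.99 WAGO locus reads per piRNA read in wild type libraries 1 to 3, against 0.186, 0.105 and 0.173 in the henn-1 libraries (exact permutation p = 0.1, the smallest possible). Wild type libraries 1 and 2 were made with a kit and the other 4 by separate adapter ligation, so protocol and genotype partly coincide. Within the separate ligation, wild type library 3 gave 8.99.

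piRNAs were shorter without henn-1. Full-length reads of 21 nt made up 74.1% ± 2.80 of piRNA reads in wild type and 25.5% ± 2.58 in henn-1. Reads of 20 nt went from 11.3% ± 0.82 to 40.6% ± 1.1 and those of 19 nt from 5.97% ± 0.58 to 22.3% ± 1.66 (each exact p = 0.1). In mean reads, 21 nt piRNAs were 1.42-fold, 20 nt piRNAs 14.9-fold and 19 nt piRNAs 15.4-fold of wild type. These folds are not scaled for depth, so 1.42-fold does not settle whether 21 nt piRNAs rose. Per piRNA with at least 20 reads in each library, the median share of 21 nt reads was 84.5% in wild type and 23.8% in henn-1, and it was lower in henn-1 at 1447 of 1570 piRNAs. Reads of WAGO loci changed less in length: 22 nt reads made up 53.6% ± 0.61 and 49.9% ± 2.20, with a mean length of 21.6 and 21.5 nt (each exact p = 0.1). Per locus with at least 20 reads in each library, the median 22 nt share was 53.1% and 50.4%, lower in henn-1 at 918 of 1188 loci.

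Fitted with edgeR over both classes, 4132 of 5412 embryo piRNAs rose and 173 fell, and 2312 of 2327 WAGO loci fell and 1 rose. The piRNAs 21ur-11755, 21ur-11351 and 21ur-8644 had no read in wild type and averaged 57.1, 42.7 and 40.2 CPM in henn-1. On this CPM scale they were 160-fold, 120-fold and 110-fold above a floor of 3 counts over the wild type group (0.356 CPM). 21ur-4031, 21ur-13940 and 21ur-13502 were 95.2-fold, 94.0-fold and 93.9-fold above this floor. CPM here is over the reads of both classes, of which piRNAs made up 19.8% ± 15.2 in wild type and 86.7% ± 3.34 in henn-1. Per piRNA read these folds would be smaller, so they are not lower bounds. 21ur-12947 fell from 21.7 ± 14.5 to 1.22 CPM (log2 -5.01, SE 0.79), and 21ur-4753 (-4.47), 21ur-9719 (-4.18), 21ur-5190 (-4.03), 21ur-10848 (-3.71) and 21ur-10492 (-3.68) followed. Among WAGO loci, C05D11.13 fell most (log2 -9.44, SE 0.65, adjusted p = 3.6e-06), then exc-9 (-8.78), gtf-2A2 (-8.61), R04A9.7 (-8.60), ins-17 (-8.18) and F10E9.2 (-8.16). Members of each list measured at WAGO loci fell throughout: 3 of 3 Argonaute genes (wago-2 -4.30, nrde-3 -2.76, alg-1 -2.08), 3 of 3 mutator machinery genes (rrf-2 -4.45, smut-1 -2.81, rde-11 -1.64), 10 of 10 histone genes (his-37 -5.72, his-31 -4.23, his-38 -3.52), 4 of 4 immune genes (pals-25 -4.85, pals-1 -4.16, pals-22 -3.86), 4 of 4 sperm genes (spe-41 -4.29, spe-15 -3.06, cpb-1 -2.67) and 3 of 3 neuron genes (egl-21 -6.77, ida-1 -2.87, unc-104 -2.0). The piRNA genes prde-1 (-4.37) and parn-1 (-3.26), the latter a piRNA-trimming nuclease, also fell. None of these lists fell beyond other WAGO loci by camera (adjusted p of 0.777 to 0.822).

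These directions rest on the joint scaling. With the WAGO table scaled by itself, 608 loci were higher and 681 lower (median 0.02), and the medians of the Argonaute (0.73), mutator (0.62), sperm (0.58), neuron (0.56) and histone (0.23) lists turned positive. With the piRNA table by itself, 1620 piRNAs were higher and 1477 lower, so higher piRNAs made up 52.3% of calls against 96.0% jointly, 85.5% with RLE factors and 83.8% with DESeq2. TMM scaling of a table with a single class centres that class near 0. The near-even splits of both tables by themselves follow from this construction and do not bear on the direction of either class. The piRNA median moved between 0.10 and 2.98 over the scalings and the WAGO median between 0.02 and -4.47.

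**Figure D4:**
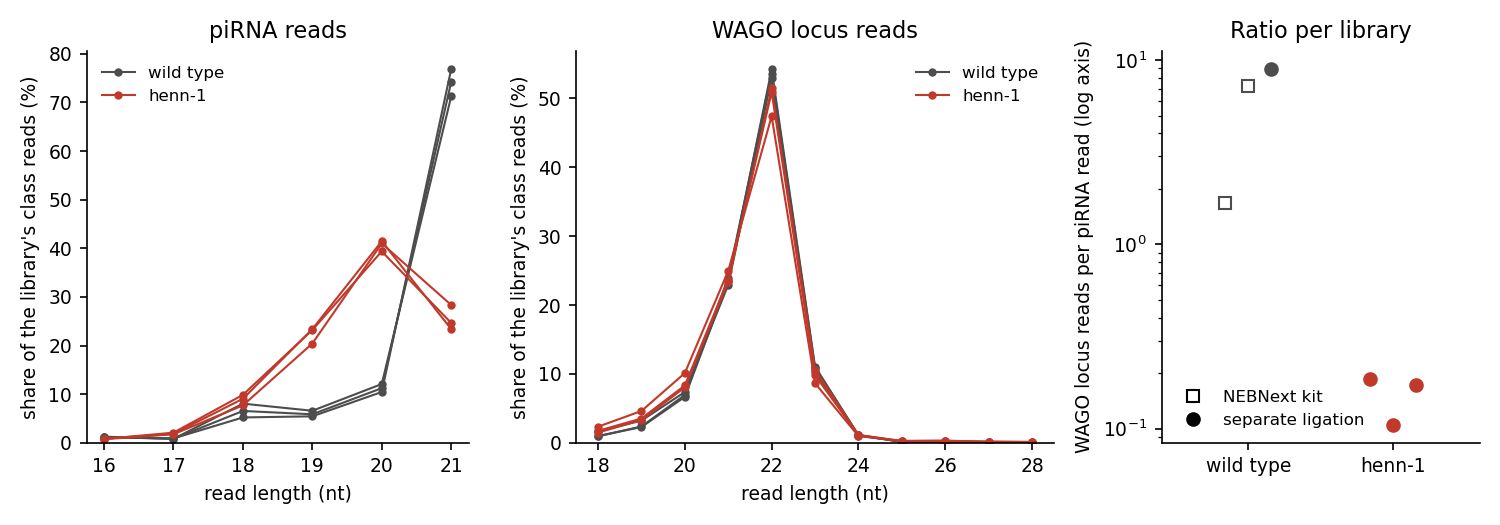
Share of piRNA reads and of WAGO locus reads by length in nt for each embryo library (lines), and WAGO locus reads per piRNA read for each library on a log axis (squares, kit; circles, separate ligation). At 21 nt the mean piRNA share was 74.1% in wild type and 25.5% in henn-1, and the ratio was at least 1.68 in wild type and at most 0.186 in henn-1.

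Periodate destroys the end of unmethylated RNAs, so the next comparison asked which small RNAs resist it and whether that needs RDE-1. The libraries of oxidized animals carry conflicting ages in the labels (gravid adults or L4 larvae), so age and oxidation may coincide. 22G-RNAs of rde-1 were 237, 224 and 303 in untreated wild type and 209, 318 and 372 in untreated rde-1 libraries. The rde-1 allele is a point mutation, so these values do not check the labels. After oxidation, they were 30.1, 11.4 and 42.8 in wild type and 123, 100.4 and 181 in rde-1. piRNAs went from 5.89% ± 0.52 to 66.7% ± 3.46 of listed reads in wild type (11.3-fold), and from 5.44% to 58.5% ± 3.37 in rde-1 (10.8-fold). ERGO-1 loci, which hold methylated 26G-RNAs, went from 0.0164% to 0.255% and from 0.0147% to 0.203%. microRNAs dropped from 46.4% ± 3.51 to 4.10% ± 1.95 and from 45.4% ± 6.93 to 7.04% ± 2.48 (each exact p = 0.1, n = 3).

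In wild type, 4176 of 5877 piRNAs rose and 52 fell, and 43 of 47 ERGO-1 loci rose. 21ur-2999 went from 358 to 35895 (log2 6.65, SE 0.16), beside 21ur-10515 (6.75), 21ur-10881 (6.53), 21ur-5594 (6.41), 21ur-930 (6.39) and 21ur-11801 (6.38). Of 215 listed microRNA arms, 194 fell and 8 rose, with miR-789 listed under a pair of names, so 7 distinct arms rose. miR-60-3p fell most (log2 -9.20, SE 1.15, 2387 to 12.1), then miR-67-3p (-7.41), miR-239a-5p (-7.39), miR-75-5p (-7.31) and miR-79-3p (-6.99). miR-1829b was listed at 0 in each oxidized library and at 85.6, 134 and 97.6 before. miR-240-5p rose from 274 ± 8.24 to 3272 ± 478 (log2 3.56, SE 0.14, adjusted p = 1.9e-07). The list of other somatic microRNAs had 44 of 46 arms lower and 1 higher, with miR-85-3p (-4.57) and miR-34-5p (-4.62) among them (camera adjusted p = 7.2e-09, and adjusted p = 0.28 with an estimated correlation). CSR-1 loci fell at 3092 of 3376 (median -2.37) and ALG-3/4 loci, which serve the male germline, at 445 of 544. Germline and meiosis genes fell at 27 of 28 (28 over the list alone), including the synaptonemal complex gene syp-4 (-2.48), htp-3 (-2.29) and the stem cell regulator fbf-1 (-2.39). Spermatogenesis genes fell at 40 of 42 (41 over the list alone), with fer-1 at -1.70 and cpb-1 at -2.10, and oogenesis genes at 26 of 30, with skn-1 at -2.25, cbd-1 at -2.39 and gld-1 at -2.60. These 3 lists had camera adjusted p = 6.7e-06 each (adjusted p = 0.28 with an estimated correlation), with medians of -2.21, -2.37 and -2.36, near that of CSR-1 loci. WAGO loci fell at 1527 and rose at 82 of 2324.

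In rde-1, 3520 of 5619 piRNAs rose and 18 fell, 39 of 46 ERGO-1 loci rose, and 154 of 211 microRNA arms fell and 3 rose. 21ur-11071 rose most (log2 7.01), then 21ur-2999 (6.86), 21ur-5594 (6.74), 21ur-12057 (6.58), 21ur-7756 (6.57) and 21ur-4445 (6.53). miR-360-5p, miR-43-3p and miR-50-3p were listed at 0 after oxidation, from 66 to 312, 68.8 to 101 and 35.5 to 59.8 before, and so was miR-70-5p (log2 -6.66, at least 64.3 before). miR-239a-5p (-6.16), miR-67-3p (-5.61), miR-60-3p (-5.34), miR-250-3p (-3.94) and lin-4-5p (-2.56, from 216452 to 37422) fell, and miR-240-5p differed by -0.24, which was not called. CSR-1 loci fell at 2294 of 3404 (median -1.41), ALG-3/4 loci at 106 of 440 (-1.89) and WAGO loci at 551 of 2314, with 161 higher (-0.22). Germline genes fell at 25 of 28 (median -1.45), with the cohesin genes coh-3 (-2.22) and coh-4 (-1.79) and the crossover gene msh-5 (-1.81). Oogenesis genes fell at 23 of 30 (cbd-1 -1.69, egg-4 -1.47, gld-1 -1.41) and mutator machinery genes at 16 of 19 (17 over the list alone), with drh-1 (-1.78), rde-11 (-1.45) and znfx-1 (-1.37). Their camera adjusted p were 6.0e-07, 3.2e-06 and 4.1e-06 (adjusted p = 0.266 with an estimated correlation). The medians of the latter lists (both -1.49) also lay near that of CSR-1 loci, so these calls do not set the lists apart from the class. 22G-RNAs of rde-1 fell (-1.15, adjusted p = 0.0158), a call that ended without rde-1 library 2 (-1.09) or 3 (-0.97).

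In all, limma called 9633 of 12383 features in wild type and 6861 of 12034 in rde-1. Higher features made up 44.9% of calls in wild type (51.3% with recovered reads) and 54.5% in rde-1 (47.5% with library totals). The median of all features was -0.32 in wild type (-0.10 with recovered reads) and 0.03 in rde-1 (-0.21 with library totals). The classes kept their direction relative to it under each scaling tried.

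The test of the difference between genotypes called 4 of 12248 features, against 1925 at an unadjusted p below 0.05 and 1 feature by the count test. miR-240-5p gained on oxidation in wild type and went from 90.7 to 85.3 in rde-1 (difference -3.80, SE 0.46, adjusted p = 0.0206). The other calls were WAGO loci: the F-box gene fbxa-207 (1.29, adjusted p = 0.0267), citk-1 (1.2, adjusted p = 0.0267), whose signal went from 1799 to 754 in wild type and from 11844 to 11303 in rde-1, and Y16B4A.2 (1.31, adjusted p = 0.0384). The median difference was 0.48 as deposited, 0.29 with library totals and 0.14 with recovered reads. Relative to the deposited median, Argonaute genes (median 1.06), nuclear RNAi genes (0.98), P granule genes (0.94), cell death genes (1.05), piRNA biogenesis genes (0.77), mutator machinery genes (0.77), the mir-51 family (1.40), the mir-35 family (1.05) and the other somatic microRNAs (1.19) were called by camera (adjusted p of 0.00226 to 0.0452, and adjusted p = 0.594 with an estimated correlation). The CSR-1 class had a median of 0.93 (quartiles 0.52 and 1.38) and the microRNA class 1.11 (0.50 and 1.48), and each of these lists lay between the quartiles of one or the other. No list was tested against its own class, so these calls do not set the lists apart from a shift of whole classes. Their members were not called over all features, except miR-240-5p. Over the list alone, 2 Argonaute genes, 2 nuclear RNAi genes, 2 P granule genes, 3 arms of mir-35 and 3 of mir-51 passed. Among named members that were not called were miR-74-3p (2.63), set-32 (2.45, adjusted p = 0.0776), lig-4 (1.98), miR-54-3p (1.65), mes-6 (1.59), miR-53-5p (1.45), miR-52-5p (1.40), ced-4 (1.40) and glh-2 (1.36). The medians of the ERGO-1 class (0.12) and the piRNA class (0.19) turned to -0.23 and -0.14 with recovered reads.

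The difference depended on single libraries. The number called was 324 without oxidized wild type library 1 and 45 without oxidized wild type library 2, and 0 to 2 without any other library. miR-240-5p passed under each scaling (adjusted over all features) and no longer without wild type library 1, 2 or 3, oxidized wild type library 3, rde-1 library 1 or 2, or oxidized rde-1 library 3 (-3.72 to -3.92). The 3 WAGO calls ended with TMM factors, library totals, no filter, the count test, the replicate block and recovered reads. They also ended without any single library (fbxa-207 1.22 to 1.34, Y16B4A.2 1.24 to 1.37, citk-1 1.15 to 1.22) other than oxidized wild type library 1 or 2, or for citk-1 rde-1 library 3. fbxa-207 and Y16B4A.2 thus passed in 4 of 20 alternatives and citk-1 in 5. set-32 passed without oxidized wild type library 1 (2.41) or 2 (2.59), and miR-52-5p, miR-54-3p, miR-90-3p and mes-6 passed without the former.

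RDE-1 was immunoprecipitated to find the microRNA arms it binds and whether this needs henn-1. In otherwise wild type animals, 42 of 156 arms were enriched and 1 depleted (n = 2 per group). miR-84-3p went from 15.7 to 14071 (log2 9.72, SE 0.94, adjusted p = 1.3e-06), miR-240-5p from 86.1 to 55560 (9.47), miR-5592-3p from 71.1 to 47576 (9.36), miR-243-3p from 32.8 to 15941 (8.88) and miR-232-5p from 3.89 to 2496 (8.88). miR-800-5p followed (8.82), and both arms of mir-243, the microRNA known to be loaded into RDE-1, were enriched. miR-237-3p (5.07), miR-85-5p (4.19), miR-793 (5.47), miR-53-5p (2.93) and miR-229-5p (2.84) were also enriched. miR-49-3p was depleted (-2.49, adjusted p = 0.0316), and let-7-5p, at 1.99, was not called (adjusted p = 0.255). By family, 2 of 6 let-7 arms, 1 of 11 mir-51 arms, 1 of 9 mir-64 arms, 6 of 38 other somatic arms and none of the 14 mir-35, 8 mir-58 or 6 mir-44 arms were enriched. The mir-35 family, abundant in oocytes and embryos, lay below the other arms (median -0.20, camera adjusted p = 0.0138, and adjusted p = 0.887 with an estimated correlation).

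In henn-1 animals, 49 listed arms were enriched and 4 depleted, and 40 were enriched in both genotypes. The identical arms of miR-789 count separately here and in otherwise wild type animals. miR-4816-3p (log2 8.49, SE 1.11), the identical arms of miR-789 (8.26), miR-232-5p (7.99), miR-5592-5p (7.94) and miR-5592-3p (7.34) led, and miR-240-5p went from 472 to 34661 (6.57). miR-237-3p (4.80), miR-85-5p (4.1), miR-82-5p (5.72), miR-36-5p (4.96), miR-51-3p (4.28), miR-66-3p (3.57), miR-53-5p (3.52), miR-229-5p (2.93) and miR-51-5p (2.87) were enriched. miR-1829b (-4.95), miR-66-5p (-3.13), miR-77-5p (-2.97) and miR-45-5p (-2.41) were depleted. No family was called by camera, with mir-44 nearest (median -0.94, adjusted p = 0.0574). For the difference between genotypes, limma called 0 of 156 arms, with 18 at an unadjusted p below 0.05 and 0 by the count test. The largest differences were miR-1829b (-4.99, adjusted p = 0.317), lin-4-5p (4.36, adjusted p = 0.317), miR-76-3p (4.10, adjusted p = 0.348), miR-234-3p (3.95, adjusted p = 0.317) and miR-243-3p (-3.89, adjusted p = 0.348). Without henn-1 input 1, 27 arms passed, miR-243-3p (-5.72) and miR-234-3p (4.97) among them, and without the RDE-1 IP 2 of otherwise wild type animals 1 passed. henn-1 input 2 listed 137 arms above 0, against 251 to 310 in the other inputs.

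Values in this set depend on the scaling chosen. The median over all arms was 0.98 as deposited, -0.26 with TMM factors and -1.09 with library totals in otherwise wild type animals, and 1.04, 0.78 and -1.25 in henn-1. Enriched arms made up 97.7%, 82.9% and 52.2% of calls in the first and 92.5%, 87.5% and 29.6% in the second. The table holds microRNA arms alone, and both scalings move all arms together, so they do not decide the direction of any family. Among named arms, calls of miR-53-5p (1.72 to 3.32) and miR-229-5p (2.20 to 3.36) ended without input 1, IP 1 or IP 2, and that of miR-49-3p without IP 1 (-1.83) or input 2 (-3.26). let-7-5p (3.57), miR-51-5p (3.81), miR-63-5p (3.6) and miR-58-3p (2.08) passed without input 2. In henn-1, miR-36-5p (2.14), miR-66-3p (1.33), miR-51-3p (1.77), miR-51-5p (2.41), miR-53-5p (3.03) and miR-229-5p (2.32) no longer passed without input 2. Without IP 1, calls of miR-66-5p (-3.32), miR-77-5p (-2.72), miR-45-5p (-2.20), miR-229-5p (3.18), miR-66-3p (3.6), miR-53-5p (3.77), miR-51-3p (3.97) and miR-51-5p (3.12) ended. Without IP 2, calls of miR-66-5p (-2.94), miR-77-5p (-3.23), miR-45-5p (-2.62), miR-229-5p (2.68), miR-66-3p (3.5), miR-53-5p (3.26) and miR-51-5p (2.62) ended, and without input 1 those of miR-45-5p (-2.67) and miR-51-5p (3.33).

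Set beside oxidation, 144 arms were measured in both kinds of table. Of 7 distinct arms that rose on oxidation in wild type, 4 were tested with RDE-1, and all 4 were enriched: miR-240-5p, miR-232-5p (oxidation 2.10 in wild type), miR-4814-3p (2.56) and miR-789 (2.06). An arm was tested only if its mean over all inputs and IPs was at least 10, so an arm low in input entered only through its IP. miR-4814-3p was at most 0.24 in any input, and miR-232-5p was 3.11 and 4.67 in the otherwise wild type inputs. The count of 4 of 4 is therefore partly set by this filter and does not tie resistance to oxidation to RDE-1. The arms not tested were miR-78 (oxidation 3.37 in wild type and 3.75 in rde-1), miR-4936 (1.68 and 1.36) and miR-2214-3p (2.84 and -0.26). Both miR-78 and miR-4936 were called higher in each genotype. miR-232-5p differed by -1.72 in rde-1, which was not called, and its difference between genotypes did not pass (-3.82, adjusted p = 0.193). Most arms enriched with RDE-1 and measured on oxidation were called lower in wild type. Among them was miR-243-3p, which fell in wild type (-1.14) and rde-1 (-1.03).

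IPs of HRDE-1 (nuclear) and WAGO-1 (cytoplasmic) asked which 22G-RNA loci each germline Argonaute binds. Both had 1 library per input and IP, so these ratios have no replicate check. WAGO loci took 67.9% of listed signal in the HRDE-1 input and 81.7% in its IP, and 76.7% and 87.5% for WAGO-1. At 2-fold enrichment and 10 CPM, HRDE-1 enriched 173 of 2434 WAGO loci and 2 of 3640 CSR-1 loci, WAGO-1 enriched 234 and 65, and 10 loci were enriched with both. These counts rest on the scaling: with RLE factors they were 698 and 27 for HRDE-1 and 550 and 228 for WAGO-1. The highest HRDE-1 ratios were at rgs-9 (3.46-fold), btb-4 (3.33) and C50E3.12 (3.32), and the lowest log2 ratios at eri-12 (-3.83), F07H5.5 (-3.64) and T08B6.2 (-3.62). The highest WAGO-1 ratios were at Y52B11A.18 (5.2-fold), bca-2 (5.17) and acdh-11 (4.51), and the lowest at ins-17 (-4.47), W04B5.1 (-4.26) and Y48G1C.6 (-4.22). Y47H10A.5, the target of mir-243, had log2 ratios of -3.07 and -2.0. The 282 WAGO loci that gained 22G-RNAs in henn-1 gonads were enriched with WAGO-1 at 22.0%, against 9.72% of all 2387 tested. Of the 140 that fell at least 4-fold, 5.0% were enriched with WAGO-1 and 8.57% with HRDE-1 (7.12% of all).

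Animals fed double-stranded RNA against pos-1, a maternal gene, were used to follow small RNAs made during RNAi, with 1 library per group. In wild type, pos-1 small RNA signal was 2860 untreated, 8267 after polyphosphatase, 7815 after periodate and 4601 after both. In glp-4 animals, which have almost no germline at the restrictive temperature of 25 C, it was 3263, 3030, 16827 and 7439. Oxidation without polyphosphatase thus gave 2.73-fold and 5.16-fold the untreated signal. By strand, polyphosphatase-treated sense reads went from 324 to 1620 on oxidation in wild type (4.99-fold) and from 462 to 465 in henn-1 (1.01-fold). Antisense reads went from 5688 to 2827 (0.497-fold) and from 5439 to 4653 (0.856-fold). The sense share rose from 5.40% to 36.4% in wild type and from 7.83% to 9.09% in henn-1. How these values were scaled between libraries is not given in the sources used here, and the difference between genotypes was not tested.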

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

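All tests of explanations given in this part, other than the splits of samples and the embryo fits by library protocol, were chosen after the results were seen. Results are listed here because an effect differed between genotypes or stages. By the test of the difference itself, miR-240-5p rose on oxidation in wild type (log2 3.56) and not in rde-1 (-0.24), a difference of -3.80. The WAGO loci citk-1, fbxa-207 and Y16B4A.2 fell in wild type (-1.26, -1.40 and -1.92) and less or not at all in rde-1 (-0.06, -0.12 and -0.62). Their differences were 1.2, 1.29 and 1.31, and these 3 calls ended with TMM factors, library totals, no filter, the count test, the replicate block and recovered reads. Of 100 splits of the 12 libraries, 6 gave as many as the real 4 calls, and the highest other split gave 1325. Chance is therefore not excluded for this count. The 5 other splits with as many calls kept the genotypes of the oxidized libraries whole while mixing those of the others, and splits that mixed the oxidized libraries gave at most 2. Such counts point to a structure of the samples, and the difference between the genotypes themselves may enter these splits.

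Stages gave henn-1 to wild type ratios of opposite sign for the named WAGO loci fer-1 and Y47H10A.5, and these differences were not tested. fer-1, which encodes a sperm fusion protein, went from 10.5 to 28.5 in embryos (log2 1.36) and from 45.7 to 40.3 at 52 h (-0.18). pals-22 went to 149 in embryos (log2 -1.42) and was near unchanged at 52 h, 52.5 and 53.2 (log2 0.0201), while 68 h (-0.60) had the sign of embryos. Y47H10A.5 went from 2.96 to 9.27 in embryos (1.38) and from 1385 to 969 at 68 h (-0.51). pos-1 small RNAs responded in opposite directions in wild type and glp-4, again with no test. Polyphosphatase gave 2.89-fold the untreated signal in wild type and 0.929-fold in glp-4. Adding periodate to polyphosphatase gave 0.557-fold in wild type and 2.46-fold in glp-4.

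The first pattern weighed is the higher number of piRNA reads in henn-1 gonads and embryos. The scaling of whole libraries could have produced it, but in gonads the values argue against this, since the median piRNA rose by 2.86 more than the median CSR-1 locus on the log2 scale, while a single factor per library would move both alike. Methylated ends might enter libraries less readily, which would also lift the 4 oxidation-resistant arms in henn-1 inputs, and the test over them did not decide (camera p = 0.108, and p = 0.242 with an estimated correlation). Between henn-1 inputs 1 and 2, miR-232-5p had 8.83 and 93.1, miR-240-5p 170 and 775 and miR-789 5.78 and 160, so the difference rests mostly on input 2, which stands apart, and miR-4814-3p was at most 0.24 in any input. A true change in piRNA level by the henn-1 genotype stays open and was not tested apart from this.

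The second pattern is the lower number of WAGO locus reads per piRNA read in henn-1 embryos. The library protocol could have contributed, yet 2328 WAGO loci were lower with protocol as a block (median -4.25), 2329 were lower within the separate ligation (median -5.31), and there the wild type library had 48.4 times the highest henn-1 ratio. These values lean against protocol as the whole cause, but the wild type side of each rests on the single library made that way, so protocol and genotype cannot be told apart. If more piRNA reads alone lowered the ratio, WAGO locus reads themselves might overlap between groups, and the lowest wild type library had 1.88 times the highest henn-1 library. Depth differed between libraries, so this stays open, as does a loss of 22G-RNAs in the henn-1 genotype. The size of any loss is not settled. In the embryo pair of the stage series (1 library per genotype, scaling not given), the henn-1 total over WAGO loci was 72.6% of wild type. The median log2 ratio was -0.69 there and -3.41 in the joint fit. rde-11 rose from 217 to 1475 there, but was called lower in the joint fit.

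The third pattern is the higher level of muscle transcripts in henn-1 gonads. Carry-over of body tissue could lift muscle, epidermis, neuron and intestine markers together, and the muscle median exceeded the highest of the other medians by 0.39. The medians were 0.80, 0.41, 0.18 and -0.58, but intestine totals ran from 132 to 620 within wild type alone, so carry-over cannot be told apart from a change in the gonad sheath or other contractile cells. The 2 libraries richest in sperm transcripts do not account for it, since the muscle median was 0.70 without them. A change by genotype stays open.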

How the results depend on the processing

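Alternatives with recovered reads, without the sperm-rich libraries, with class totals leaving out each replicate, with an estimated correlation and with crossed numbers were added after seeing the data. Named features kept direction and call in 362 of 364 settings for gonad small RNAs, 319 of 348 for gonad mRNAs, 364 of 364 and 362 of 364 for oxidation in wild type and rde-1, 440 of 500 for its difference, 308 of 334 and 250 of 310 for RDE-1 enrichment without and with the henn-1 mutation, 231 of 240 for stages, 164 of 164 for embryo piRNAs and 353 of 364 for embryo WAGO loci. No filter gave 9464 gonad small RNA calls and 81 arms in henn-1 IPs, where more features are tested. For mRNAs, 971 calls were made without both sperm-rich libraries, 847 of them shared with the 1733. The oxidation difference had 1 call with TMM, library totals, no filter, the count test, the block and recovered reads, and 6 with a pseudocount of 10. Library totals gave 98 arms in henn-1 IPs, and stages gave 454 loci with TMM and 461 with totals. Leaving out each library in turn gave 4918 to 5657 gonad small RNAs, 676 to 1737 mRNAs, 8262 to 10090 features for oxidation in wild type and 4923 to 6895 in rde-1, 29 to 57 arms with RDE-1 and 41 to 70 with RDE-1 in henn-1, 3468 to 4200 embryo piRNAs and 2307 to 2328 embryo WAGO loci. The oxidation difference ranged from 0 to 324 calls, with 324 without oxidized wild type library 1 and 45 without library 2. The RDE-1 difference ranged from 0 to 27, with 27 without henn-1 input 1. Leaving out each stage gave 561 to 1301 loci. With each embryo table by itself, 1289 WAGO loci were called. Of the named loci alone, 9 reversed: smut-1 0.62, rde-11 1.74, cpb-1 0.78, nrde-3 0.73, alg-1 1.39, ida-1 0.56, unc-104 1.45 and, not called there, spe-15 0.39 and parn-1 0.16. This follows from the construction, since the median change of that table by itself was 0.02. Embryo piRNAs by themselves gave 3097 calls, with 1791 of the 2014 shared calls in the same direction, and WAGO loci kept 682 of 1275. Scaling by itself centres the piRNA table as well, so its changes of direction also follow from the construction. Without microRNAs in the denominator, log2 class shares on oxidation were -3.24 (ALG-3/4), -2.78 (CSR-1), 3.12 (ERGO-1), -1.36 (WAGO) and 2.66 (piRNA) in wild type and -2.31, -2.20, 2.98, -1.07 and 2.64 in rde-1. Gene lists past the threshold numbered 0 with an estimated correlation in gonad small RNAs, gonad mRNAs, oxidation in wild type, in rde-1, its difference and RDE-1 IPs. With fry they numbered 11 in gonad small RNAs, 11 in gonad mRNAs, 23 and 20 for oxidation in wild type and rde-1, 7 for its difference, 0 in RDE-1 IPs, 2 across stages and 6 in embryo WAGO loci. Enriched WAGO and CSR-1 loci were 0 and 0 with HRDE-1 at 4-fold, 100 and 1 at 100 CPM and 698 and 27 with RLE. With WAGO-1 they were 10 and 1, 137 and 11, and 550 and 228. Per all listed pos-1 reads, oxidation folds were 6.75 (sense) and 0.672 (antisense) in wild type and 1.16 and 0.986 in henn-1. Except where the construction is named, the cause was not tested. The replicate numbers are not known to pair samples (correlations from -0.60 to 0.45). With the replicate number as a block, calls were 5429 (gonad small RNA), 1456 (mRNA), 9460 and 7292 (oxidation in wild type and rde-1), 1 (difference), 45, 52 and 0 (RDE-1), 4427 (embryo piRNAs) and 2315 (embryo WAGO loci). Apart from the oxidation difference, the block moved no count by more than 1.5 times. Every sample correlated best with its own number in wild type oxidation and in the henn-1 RDE-1 libraries, and not in the other comparisons. With 2 libraries per group, either all or none of the RDE-1 numbers can match, so that match does not bear on pairing. The numbers of RDE-1 inputs crossed gave 44. Fits on 4 libraries of a genotype gave 44 and 49 arms, and cannot give the RDE-1 difference. Read depth is not given for the RDE-1, stage, HRDE-1 and WAGO-1 sets, whose listed totals are the lowest (66278 to 678659), so calls at low values are least certain there.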

Other observations

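Within-WAGO control tests, splits of libraries for the microRNA arms and abundance checks, and the test on RDE-1-bound arms, were chosen after the results were seen. Loci that lost 22G-RNAs in gonads include several genes of signalling and metabolism that were named after their values were seen. asah-1, an acid ceramidase gene, had log2 changes of -3.49 in gonads and -2.49 across stages, and comt-3, a methyltransferase gene, had -3.60 and -2.04. The choline kinase gene ckb-4 (-3.17 and -2.21), the glutathione peroxidase gene gpx-6 (-3.27 and -2.08) and sma-3 (-2.17 and -2.44), a Smad of the body size pathway, moved alike. In embryos with both classes scaled jointly these loci had -6.94, -6.16, -7.15, -7.15 and -6.45.

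The WAGO-1 ratios of strongly lost loci varied. Over the 140 loci down at least 4-fold the median log2 ratio was -0.48 with WAGO-1 and 0.48 with HRDE-1, against 0.07 and 0.31 over all tested. The WAGO-1 ratio was -3.50 at Y34D9A.8, -2.91 at F10E9.2 and -2.31 at gtf-2A2, but 0.08 at R04A9.7, 0.52 at asah-1 and 0.54 at C27C7.7. These come from 1 library each and have no replicate check.

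The first hypothesis, written before its result was seen, was that mRNAs of WAGO loci whose 22G-RNAs fell at least 2-fold rose. Of 276 such mRNAs, 23 rose and 3 fell (median 0.11 against 0.02 of all mRNAs, camera p = 0.0148, and p = 0.00954 with an estimated correlation). Against 967 mRNAs of other WAGO loci, whose median was 0.07 with 86 risen and 60 fallen, the camera test of the same 276 did not pass. The test may reflect WAGO loci as a whole and does not tie the mRNA change to the loss of 22G-RNAs. The second hypothesis, also written before, was that mRNAs of loci that gained 22G-RNAs at least 2-fold fell. Of 38 such mRNAs, 6 rose and 3 fell (median 0.15 against 0.02 of all mRNAs, camera direction up, p = 0.0743, and p = 0.105 with an estimated correlation). This meets the outcome written before as going against the hypothesis, which named no p. The camera test did not pass, so the hypothesis is left open. rde-11 (-0.66) and tpk-1 (-0.51) are single genes whose mRNA did fall.

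A further hypothesis was that arms bound by RDE-1 resist oxidation less in rde-1 than in wild type. The 37 enriched arms had a median difference of 0.25 against 1.2 for 109 other arms (camera p = 1.8e-09, and p = 0.00221 with an estimated correlation), and p = 3.5e-09 without miR-240-5p. Yet 10 of 100 splits of the libraries, the real split among them, gave a gap as large as -0.93, up to 1.06 in size. Labels were shuffled between the genotypes, so the difference between the genotypes themselves may enter these splits. They therefore cannot decide whether the gap is due to chance. At values of at least 1000, 11 enriched arms had 0.78 and 65 others 1.2. The gap might come from the structure of the samples, and the data cannot tell this from an effect of RDE-1.

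For the comparisons of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05, with the real split the 1 that gave as many calls in each. Calls in the real split and the highest other were 5477 and 0 for gonad small RNAs, 1733 and 12 for gonad mRNAs, 9633 and 0 for oxidation in wild type, 6861 and 0 in rde-1, 4305 and 0 for embryo piRNAs and 2313 and 0 for embryo WAGO loci.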
